A study of Eggerthella lenta DSM 2243 with 22 samples.

How the data were processed

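RNA from Eggerthella lenta DSM 2243 was sequenced on an Illumina Genome Analyzer II after depletion of ribosomal RNA and random-primed cDNA synthesis, per the labels. Cultures differed in growth phase (exponential or stationary), arginine (0.25% or 1.25%) and digoxin (0 or 10 µg/ml), giving 22 libraries in 8 groups. The exponential groups and the stationary groups at 0.25% arginine with digoxin and at 1.25% arginine without it had 3 libraries each, and the other 2 stationary groups had 2 each. The labels do not say whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries only.

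Each deposited table listed, for 1 library, the genes with reads, an expected count per gene and a fraction. The deposited expected counts are estimates that can be fractional where reads were shared between genes, and genes with many fractional counts are therefore uncertain. The deposited fraction was each gene's share of the library's total and was used only to check the counts, from which it differed by at most 4.8e-05 in relative terms. The aligner, the counting program and the genome build were not given in the sources used here. Genes missing from a table were taken to have 0 counts, which gave 3031 features over all libraries. No reference genome was used here.

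Exponential libraries held between 293488 and 889093 counts, and stationary libraries between 160 and 114105. By group the stationary totals were 31662 and 56795 (0.25% arginine, no digoxin), 19268, 45227 and 114105 (0.25%, digoxin), 3436, 7919 and 12700 (1.25%, no digoxin), and 781 and 160 (1.25%, digoxin). At 1 count, the lowest level seen was therefore near 1 to 3 CPM in an exponential library and far higher in a shallow one. Libraries of a group were compared for copies by a chi-square test per pair, and the statistic over its degrees of freedom lay between 2.54 and 27.3, so no 2 libraries of a group were copies of each other.

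Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and 1 mean per group was fitted by quasi-likelihood with robust dispersion. Comparisons within a phase used the libraries of that phase, and comparisons between phases used all 22. The fits held 2018 genes for the 12 exponential libraries, 464 for the 10 stationary libraries and 2355 for all, with common biological coefficients of variation of 0.223, 0.393 and 0.249. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05 at any fold. Standard errors were taken as the log2 fold over the square root of F and are approximate. The comparisons were digoxin against none in each phase and arginine concentration, 1.25% against 0.25% arginine in exponential cultures with and without digoxin and in stationary cultures without it, stationary against exponential cultures without digoxin at each concentration, and 2 differences between digoxin effects (between arginine concentrations, and between phases at 0.25% arginine).

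Gene lists were matched on the product names in the tables, and lists with 3 or more tested members were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation. The lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined. By that rule the genes named were Elen_2528 and Elen_2529, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 10 counts in the higher group, the 3 members with the smallest p of each list called, all members of the arginine deiminase pathway in arginine comparisons, and the 5 genes with the smallest p of a difference between effects. Only part of the genes under this rule are described, and genes outside it are said to be so. In the list of named genes the names cgr1 and cgr2 had been attached the wrong way round (Elen_2529 encodes the flavoprotein usually called cgr2), so both are given by locus tag. The pattern for the DNA damage list also matched within the word pyruvate, which put 11 enzymes of pyruvate use among its 24 genes.

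Where a group had 0 counts, the fold is given as at least the value obtained with 3 counts in its place, and where it had 1 to 3 counts, as a count ratio with an exact 95% interval, both over the sum of a group and on library totals without scaling factors. These floors and intervals cover counting error only, and reads copied during amplification are not independent molecules.

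The fits were tested on simulated data made from these libraries with known changes. Counts were drawn from the fitted model itself, with a spread set by a gene's level alone and not by its library or group. Real spread can differ by gene and by group, so the real calls may be false more often than these rates. In the 4 exponential comparisons of 2 groups, 55.1% to 66.7% of 2-fold and 92.9% to 99% of 4-fold changes were recovered, with 1% to 3.7% of calls false. For the difference of digoxin effects between arginine concentrations 20% and 75.5% were recovered (5.1% of calls false), and for that between phases 2.1% and 22.1% (4.2%). In stationary cultures at 0.25% arginine the digoxin test recovered 14.9% of 2-fold and 66.7% of 4-fold changes, and at 1.25% arginine 0% and 5.4%. Between phases TMM gave 18.3% false calls at 0.25% and 84.5% at 1.25% arginine, against 9.2% and 6.3% with library totals. The median log2 fold of unchanged genes there was -0.36 and -0.99 with TMM, against -0.21 and -0.23 with library totals. Both groups compared were simulated from the same pooled profile, without the wide differences of the real phases. That setting favours library totals, so these rates do not rank the scalings for the real data. Since the scalings differed, single genes are described in the phase comparisons only where scalings gave the same direction.

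The alternatives tried were DESeq2 size factors in edgeR, upper-quartile scaling, no filter, a stricter filter (10 counts in every library of a group compared), DESeq2 1.42.0, limma voom with quality weights, all 22 libraries or only the groups compared in the fit, and leaving out each library in turn. Library totals in place of TMM, and minimum library totals of 1000 and 10000 counts, were added after the data had been seen. Calls with all splits of the libraries of 2 groups into groups of equal size were also computed, as were counts of neighbouring called genes. For the difference of digoxin effects between arginine concentrations, only a random sample of the splits was fitted. The list of tables was read with jsonlite 2.0.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the main comparisons. Arginine in stationary cultures with digoxin, and phase in cultures with digoxin, were not among the comparisons chosen and were not analysed here.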

Results

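Transcript counts of Eggerthella lenta DSM 2243 were compared between cultures with and without 10 µg/ml digoxin, at 0.25% and 1.25% arginine, in exponential and in stationary phase. Changes are given as log2 folds with their standard errors (SE), levels as means of CPM (a gene's counts per 1000000 counts of its library) with standard deviations (SD), and n as the number of libraries in a group. A gene was called, and is said to have risen or fallen, where its adjusted p in edgeR was under 0.05.

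Elen_2528 and Elen_2529, the adjacent genes of the cardiac glycoside reductase (cgr) operon, which is known to be induced by digoxin and needed for its reduction, had the largest increases with digoxin of the 2018 genes tested in exponential cultures. At 0.25% arginine Elen_2528 stood at 782 CPM (SD 130, n = 3) with digoxin and at 1.99 CPM (SD 1.79, n = 3) without it, where only 2 counts were found. That is a count ratio of 454 (exact 95% interval 126 to 3750; log2 fold 8.70, SE 0.41, adjusted p = 7.04e-10). Elen_2529 stood at 2723 CPM (SD 372) against 17.1 CPM (SD 4.41), 159-fold higher (log2 fold 7.31, SE 0.27, adjusted p = 4.07e-11). At 1.25% arginine Elen_2528 stood at 505 CPM (SD 22.5, n = 3) against 2.06 CPM (SD 1.84, n = 3), a log2 fold of 7.92 (SE 0.37, adjusted p = 6.66e-10). Elen_2529 stood there at 1799 CPM (SD 85.6) against 4.70 CPM (SD 1.998), a log2 fold of 8.53 (SE 0.30, adjusted p = 1.49e-11). In stationary cultures at 0.25% arginine Elen_2529 reached 14260 CPM (SD 6699, n = 3) with digoxin against 61.6 CPM (SD 87.2, n = 2), a log2 fold of 7.58 (SE 0.95, adjusted p = 5.95e-13). Elen_2528 reached 6245 CPM (SD 2361) there against 3 counts without digoxin, a count ratio of 146 (exact 95% interval 49.8 to 709; adjusted p = 3.08e-14). These 6 calls held in every fit that left out 1 library of the groups compared. In stationary cultures at 1.25% arginine the 2 digoxin libraries held 941 counts in all, of which Elen_2528 had 1 and Elen_2529 had 0 (adjusted p = 0.506 and 0.785). A count of 0 there allows up to 3190 CPM by counting error. That is under the 7738 CPM of the lowest stationary 0.25% arginine digoxin library. It is above the 1799 CPM of exponential 1.25% arginine cultures with digoxin, so whether Elen_2529 rose in that group was not determined. Elen_2528 had fractional counts, a sign of reads shared with other genes, in 83.3% of the exponential libraries.

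**Figure D1:**
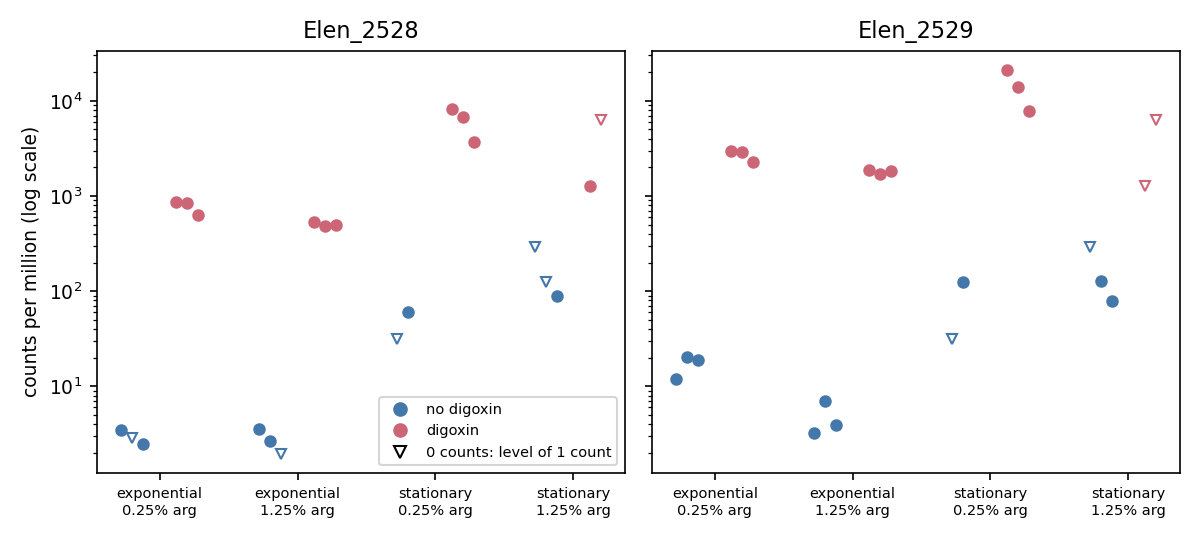
CPM (log scale) of Elen_2528 and Elen_2529 in each library, by growth phase and arginine, without (blue) and with (red) digoxin; open triangles mark libraries with 0 counts, drawn at the level of 1 count. In exponential cultures the means of Elen_2529 rose from 17.1 to 2723 CPM at 0.25% arginine and from 4.70 to 1799 CPM at 1.25% arginine.

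In exponential cultures at 0.25% arginine, digoxin was also followed by higher counts of a run of genes, Elen_3048 to Elen_3051, annotated as a membrane protein, a hypothetical protein, a ferredoxin and a molybdopterin oxidoreductase. Elen_3048 rose from 6.26 CPM (SD 4.62, n = 3) to 87.6 CPM (SD 41.5, n = 3), a log2 fold of 3.83 (SE 0.59), and Elen_3049 by a log2 fold of 3.37 (SE 0.52). The ferredoxin Elen_3050 (log2 fold 3.09, SE 0.32) and the oxidoreductase Elen_3051 (log2 fold 3.06, SE 0.27) rose alongside. The hypothetical genes Elen_2125 (log2 fold 4.17, SE 0.47) and Elen_0275 (log2 fold 4.14, SE 0.57) rose, and Elen_0274 rose from 1 count to 103 (count ratio 47.2, exact 95% interval 8.29 to 1880). The acetate/CoA ligase Elen_0706 rose from 1330 CPM (SD 309) to 15200 CPM (SD 3481), and its neighbour Elen_0707 rose by a log2 fold of 2.54 (SE 0.21). Among the genes that fell were glutamine synthetase Elen_2016 (log2 fold -1.56, SE 0.16), its neighbour and 2-component regulator Elen_2015 (log2 fold -1.58, SE 0.23) and the ammonium transporter Elen_2526 (log2 fold -1.81, SE 0.27). The ABC transporter gene Elen_0741 (2.64-fold lower) and the MFS transporter gene Elen_2815 (log2 fold -1.37, SE 0.19) fell as well. Of 2018 genes tested by edgeR, 59 were called, 31 higher and 28 lower. Each gene named in this paragraph was among the 22 (15 higher, 7 lower) that stayed called without any 1 of the 6 libraries. The count itself moved to 35 without replicate 1 and 34 without replicate 2 of the cultures without digoxin, and to 127 without replicate 3 of the digoxin cultures.

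No list of genes by function was called at 0.25% arginine by the camera test, at the preset correlation or with an estimated one. The list of 12 neighbours of the cgr operon had 6 members with enough counts, of which the ammonium transporter Elen_2526 fell, 0 rose and 5 were not called, against 1 higher and 1 lower adjusted over the list alone. No member of the drug efflux list (12 tested), the LuxR regulators (60 tested), the ribosomal proteins (51 tested) or the arginine deiminase pathway (7 tested) was called, against 2 higher in the pathway list adjusted over the list alone. Of 116 other transcriptional regulators tested, 0 rose, 6 fell and 110 were not called, against 2 higher and 8 lower adjusted over the list alone.

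At 1.25% arginine the same genes Elen_3049, Elen_3050 and Elen_3051 rose with digoxin in exponential cultures, Elen_3051 from 130 CPM (SD 36.0, n = 3) to 1393 CPM (SD 345, n = 3), a log2 fold of 3.49 (SE 0.28). Elen_2125 rose from 4.43 CPM (SD 2.45) to 269 CPM (SD 106), and Elen_0273, Elen_0274 and Elen_0275 rose by log2 folds of 4.71 (SE 0.73), 4.77 (SE 0.57) and 3.67 (SE 0.43). Glutamate decarboxylase Elen_0149, known in other bacteria for acid resistance (log2 fold 3.19, SE 0.40), and ornithine carbamoyltransferase Elen_0670 (16-fold, 2.38 to 34.3 CPM) rose here. A run of genes from Elen_0737 to Elen_0742 fell, annotated as a histidine kinase, a 2-component regulator, an ABC transporter and hypothetical or unknown proteins. In that run Elen_0740 fell from 2187 CPM (SD 273) to 328 CPM (SD 79.7), a log2 fold of -2.61 (SE 0.25), and Elen_0742 by a log2 fold of -2.52 (SE 0.27). Glutamyl-tRNA reductase Elen_2071 (log2 fold -1.37, SE 0.24), siroheme synthase Elen_2072 (log2 fold -1.23, SE 0.24) and the radical SAM gene Elen_2068 (log2 fold -0.99, SE 0.17) fell too. The ferredoxin Elen_1738 (log2 fold -3.10, SE 0.46) and the nitrite reductase Elen_2586 (log2 fold -1.75, SE 0.32) also fell. Of 2018 genes tested by edgeR, 60 were called, 30 higher and 30 lower, against 24 higher and 39 lower with library totals in place of TMM. Each gene named in this paragraph was among the 27 (15 higher, 12 lower) that stayed called without any 1 of the 6 libraries. The count moved to 32 and 28 without replicates 1 and 2 of the cultures without digoxin, and to 39, 39 and 35 without replicates 1, 2 and 3 of the digoxin cultures.

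At 1.25% arginine 3 lists were called by camera at the preset correlation, and each call was lost with an estimated correlation. Of 51 ribosomal proteins, 50 had a log2 fold above 0 and the median was 0.42 (adjusted p = 6.83e-06, adjusted p = 0.927 with an estimated correlation). Only L11 Elen_2129 was called higher (log2 fold 0.71, SE 0.18, adjusted p = 0.0472), 0 were called adjusted over the list alone, and the L11 call was lost in each of the 6 fits without 1 library. Of 60 LuxR regulators 0 rose, 1 fell and 59 were not called (adjusted p = 0.0088, adjusted p = 0.241 with an estimated correlation). The member that fell, Elen_1291 (log2 fold -1.81, SE 0.46), was likewise called in none of those 6 fits. Of 16 flavin reductases only the cgr gene Elen_2529 rose and 15 were not called (adjusted p = 0.00902, adjusted p = 0.241 with an estimated correlation). Of the arginine deiminase pathway 1 of 7 tested members rose (Elen_0670), 1 fell (Elen_0676) and 5 were not called, the same adjusted over the list alone (camera adjusted p = 0.902). Elen_0676 stood at 1.37 CPM with digoxin against 14.9 CPM, on counts of 0.5 and 1 per library that rounding took to 1 in all (count ratio 25.9, exact 95% interval 4.31 to 1060, over 2 times the ratio of the means), and its call was lost without replicate 2 of the cultures without digoxin (adjusted p = 0.0609) and without replicates 1, 2 and 3 of the digoxin cultures (adjusted p = 0.142, 0.0712 and 0.0515). The cgr neighbours had 0 of 6 called, against 1 higher adjusted over the list alone.

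The digoxin responses at the 2 arginine concentrations overlapped, in comparisons that shared no library but came from the same fit, with a common estimate of the spread. The Fisher tests take genes as independent, though called genes often lay in runs, so their p-values can be too small. Of the genes called higher, 15 were shared (0.46 expected for independent calls, Fisher p = 1.5e-21). They included Elen_2528, Elen_2529, Elen_2125, Elen_0274, Elen_0275 and Elen_3048 to Elen_3051. Of the genes called lower, 11 were shared (0.42 expected, Fisher p = 1.8e-14), among them glutamine synthetase Elen_2016 and porphobilinogen synthase Elen_2067. The call of Elen_2067 was lost without replicate 1 of either 0.25% arginine group and without replicate 2 of the 1.25% arginine digoxin cultures. No gene was called in opposite directions. In both comparisons 12 genes stayed called without any 1 library, 9 higher and 3 lower. They included the sigma factor gene Elen_2728, higher at 0.25% (log2 fold 2.32, SE 0.32) and at 1.25% arginine (log2 fold 1.64, SE 0.29), and the regulator gene Elen_0738, lower at both (log2 folds -0.95, SE 0.18, and -1.55, SE 0.19). The genes Elen_0149, Elen_0707, Elen_0737, Elen_0738, Elen_2067, Elen_2068, Elen_2071, Elen_2072, Elen_2586, Elen_2728, Elen_3050 and Elen_3051 were outside the naming rule in 1 or both of these comparisons and were chosen after their values were seen.

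**Figure D2:**
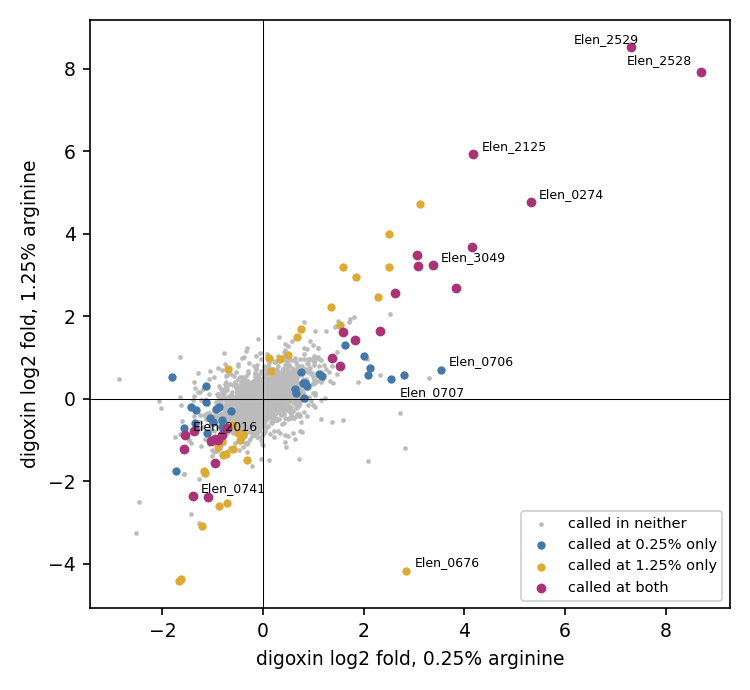
Log2 fold with digoxin of each of 2018 genes in exponential cultures at 0.25% arginine (horizontal axis) and at 1.25% arginine (vertical axis), coloured by where the gene was called. Of the called genes, 15 rose and 11 fell at both concentrations, while Elen_0706 rose by a log2 fold of 3.53 at 0.25% arginine alone.

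For 7 genes the digoxin effect itself differed between the arginine concentrations (edgeR interaction, 2 with a positive and 5 with a negative difference). Elen_0706 rose 11.5-fold with digoxin at 0.25% arginine, while at 1.25% arginine it went from 19890 CPM (SD 2280, n = 3) to 30370 CPM (SD 2632, n = 3), a difference in log2 fold of -2.83 (SE 0.33, adjusted p = 0.000581). Elen_0707 went the same way (difference -2.06, SE 0.28, adjusted p = 0.00175). For the ammonium transporter Elen_2526 the fall seen at 0.25% arginine was absent at 1.25%, where the means were 72.7 CPM without and 98.0 CPM with digoxin (difference 2.33, SE 0.41, adjusted p = 0.0178). The other 4 genes were Elen_0676, Elen_0740, Elen_0742 and L11 Elen_2129, which were not called in 6, 8, 8 and 9 of the 12 fits without 1 library. A gene that failed the count filter of a fit was taken as not called, as Elen_0676 was in some of them. The count of 7 moved to 3 and 3 without replicates 1 and 2 of the 0.25% arginine cultures without digoxin, to 3, 4 and 4 without replicates 1, 2 and 3 of the 1.25% arginine cultures without digoxin, and to 2 and 2 without replicates 2 and 3 of those with digoxin. Elen_0706 and Elen_0707 stayed called in all 12 of these fits. The call of Elen_2526 was lost without replicate 1 of the 0.25% arginine cultures without digoxin (difference 2.05, adjusted p = 0.0716) and without replicates 2 and 3 of the 1.25% arginine digoxin cultures (differences 2.28 and 2.21).

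**Figure D3:**
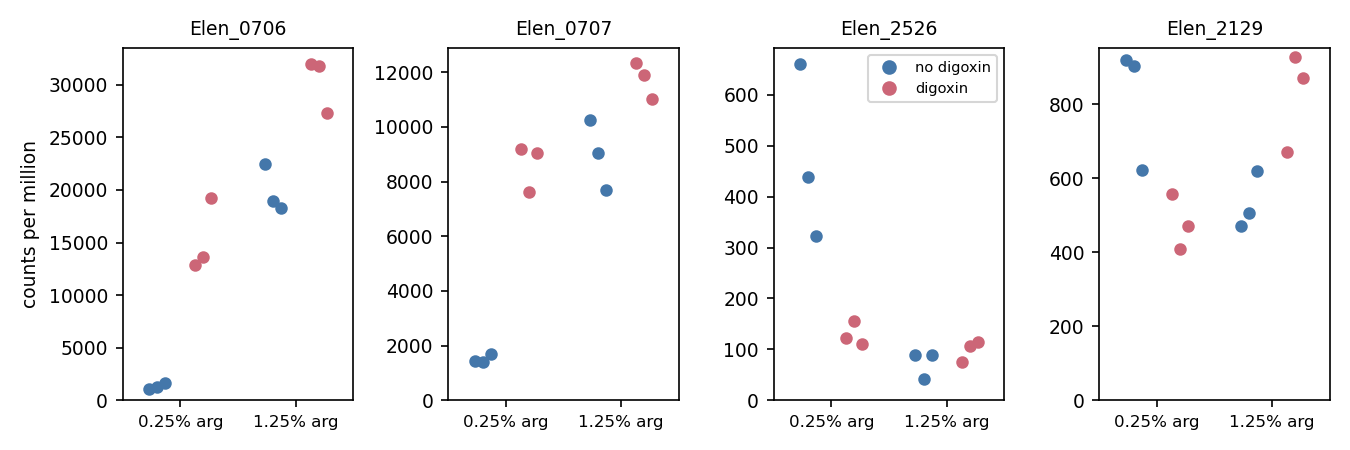
CPM of 4 genes whose digoxin effect differed with arginine, in each exponential library without (blue) and with (red) digoxin. Elen_0706 and Elen_0707 were low only in the 0.25% arginine cultures without digoxin (1330 and 1512 CPM), and Elen_2526 was high only there (475 CPM).

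In exponential cultures without digoxin, the run Elen_0690 to Elen_0699, which holds the genes annotated as an Rnf electron transport complex, known in other bacteria to couple ferredoxin oxidation to ion transport, was lower at 1.25% than at 0.25% arginine. Subunit E Elen_0696 fell from 648 CPM (SD 129, n = 3) to 140 CPM (SD 38.6, n = 3), a log2 fold of -2.37 (SE 0.39), and the FMN-binding gene Elen_0697 by a log2 fold of -2.41 (SE 0.39). Of these 10 genes all were called lower, and 8 stayed called without any 1 of the 6 libraries. Elen_0692 was not called without replicates 1 and 2 at 0.25% and replicates 1 and 3 at 1.25% arginine, and Elen_0699 not without replicate 3 at 0.25% and each replicate at 1.25% arginine. The ammonium transporter Elen_2526 fell from 475 CPM (SD 172) to 72.7 CPM (SD 26.8), a log2 fold of -2.88 (SE 0.29). Its neighbour, the nitrogen regulatory protein P-II gene Elen_2525, fell (log2 fold -1.96, SE 0.33), as did glutamine synthetase Elen_2016 (log2 fold -1.39, SE 0.16). The aldehyde ferredoxin oxidoreductase Elen_2089 (log2 fold -2.98, SE 0.48) and the cysteine desulfurase Elen_2091 (log2 fold -3.09, SE 0.59) also fell. Elen_0706 rose from 1330 CPM (SD 309) to 19890 CPM (SD 2280), a log2 fold of 3.71 (SE 0.26). The peptidylprolyl isomerase Elen_2350 (log2 fold 1.53, SE 0.22) and the membrane protein gene Elen_2501 of unknown function (log2 fold 1.54, SE 0.30) rose too.

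Of 2018 genes tested by edgeR for arginine without digoxin, 156 were called, 57 higher and 99 lower at 1.25% arginine. Library totals gave 114 higher and 61 lower with a median of all genes 0.18 higher, so the split by direction was not fixed by these data, and 40 genes (12 higher, 28 lower) stayed called in every fit without 1 library. Without replicate 2 at 0.25% arginine the count was 102, and without replicates 1, 2 and 3 at 1.25% arginine it was 54, 86 and 44. All 5 members of the NADH dehydrogenase list fell, with a median log2 fold of -1.14 (camera adjusted p = 2.61e-06, adjusted p = 0.35 with an estimated correlation) and 5 lower adjusted over the list alone. The largest fall was in Elen_1571 (log2 fold -1.49, SE 0.32), whose call was lost without replicates 1 and 3 at 1.25% arginine (adjusted p = 0.0544 and 0.0614), while that of Elen_1574 (log2 fold -1.14, SE 0.20) held in every such fit. Elen_1570 and Elen_1572 lost theirs without the same 2 libraries, and Elen_1255 also without replicates 2 and 3 at 0.25% arginine. None of the 7 tested members of the arginine deiminase pathway was called, nor were any adjusted over the list alone. Arginine deiminases Elen_0153 and Elen_1949 stood at 27210 CPM (SD 4580) and 27920 CPM (SD 3263) at 0.25%, and at 26620 CPM (SD 691) and 23780 CPM (SD 2114) at 1.25% arginine. The 5 called members of the list named for the DNA damage response all fell (6 adjusted over the list alone), but 4 of them are enzymes of pyruvate use that do not act in DNA repair: the oxidoreductases Elen_1583, Elen_1703 and Elen_1705 and the dikinase Elen_1387. The fifth was the repressor LexA Elen_1611, and the list was not called (camera adjusted p = 0.0891). All 5 lost their calls without replicates 1 and 3 at 1.25% arginine, and Elen_1611 also without replicate 2 there or replicate 3 at 0.25%. Of the cgr neighbours, 2 fell (Elen_2525 and Elen_2526) and 4 were not called.

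With digoxin present, the fall of the Elen_0690 to Elen_0699 run at 1.25% arginine was seen again. Rnf subunits Elen_0694 and Elen_0695 fell by log2 folds of -1.96 (SE 0.28) and -1.91 (SE 0.32), and 9 of the 10 genes were called lower, all but Elen_0692. The other 7 lost their calls without 1 or more of replicates 2 and 3 at either concentration, and Elen_0691 also without replicate 1 at 1.25% arginine. The run Elen_0738 to Elen_0742 fell, Elen_0740 from 2143 CPM (SD 564, n = 3) to 328 CPM (SD 79.7, n = 3), a log2 fold of -2.80 (SE 0.26). The oxidoreductase Elen_3051, higher with digoxin at both concentrations, was lower at 1.25% than at 0.25% arginine with digoxin (log2 fold -1.51, SE 0.25) and without it (log2 fold -1.94, SE 0.27). The cgr gene Elen_2529 was lower at 1.25% arginine with digoxin (log2 fold -0.72, SE 0.18, adjusted p = 0.0436) and without it (log2 fold -1.94, SE 0.42, adjusted p = 0.0114). The call with digoxin was lost without replicate 2 at 0.25% and replicates 2 and 3 at 1.25% arginine, and that without digoxin without replicate 3 at 0.25% and replicates 1 and 3 at 1.25% arginine. Of 2018 genes tested by edgeR, 74 were called, 21 higher and 53 lower, against 35 higher and 38 lower with library totals, which moved the median of all genes by 0.12. The genes shared with the comparison without digoxin were 8 higher (0.59 expected, Fisher p = 3.8e-08) and 36 lower (2.6 expected, Fisher p = 1.3e-37), with none opposite. These Fisher p-values can likewise be too small, since called genes lay in runs and the same fit gave both comparisons. In every fit without 1 library, 8 genes stayed called, all lower: Elen_0694, Elen_0695, Elen_3051 and Elen_0738 to Elen_0742. Without replicates 1, 2 and 3 at 0.25% arginine the count was 185, 21 and 26, and without replicates 2 and 3 at 1.25% arginine 19 and 8.

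Of the NADH dehydrogenase list, 3 of 5 members fell with digoxin present and 2 were not called, against 5 lower adjusted over the list alone (median log2 fold -1.11, camera adjusted p = 1.03e-05, adjusted p = 0.45 with an estimated correlation). Calls of these members were not stable to leaving out libraries. Elen_1574 (log2 fold -0.85, SE 0.20) was not called without replicate 2 or without replicate 3 at either concentration (adjusted p from 0.0699 to 0.153). Its log2 fold stayed between -0.89 and -0.69 in those fits. Of the 51 ribosomal proteins 0 were called, 43 had log2 folds above 0 and the median was 0.18 (camera adjusted p = 0.0103, adjusted p = 0.903 with an estimated correlation). In the arginine deiminase pathway 1 of 7 tested members fell, the weakly counted ornithine carbamoyltransferase Elen_0676 (19.6 to 1.37 CPM, and after rounding 49 counts to 1, a count ratio of 33.7 with an exact 95% interval of 5.76 to 1360, over 2 times the ratio of the means), a call lost without replicate 3 at either concentration. The genes Elen_0690 to Elen_0695, Elen_0698, Elen_0699, Elen_0738, Elen_0741, Elen_1387, Elen_1583, Elen_1611, Elen_1703, Elen_1705, Elen_2016, Elen_2525, Elen_2529 and Elen_3051 were named in the arginine comparisons after their values were seen.

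**Figure D4:**
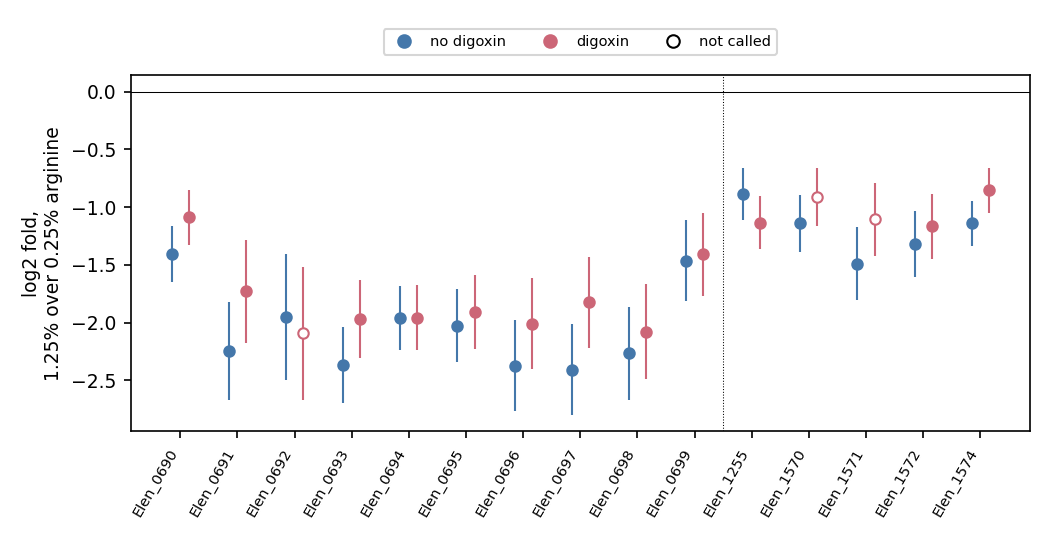
Log2 fold at 1.25% over 0.25% arginine in exponential cultures without (blue) and with (red) digoxin for Elen_0690 to Elen_0699 and, right of the dotted line, the NADH dehydrogenase list; bars are 1 SE and open points were not called. All points lie below 0, down to -2.41 for Elen_0697.

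In stationary cultures 464 genes passed the count filter, which was set over all 10 stationary libraries, the shallow 1.25% arginine ones included. At 0.25% arginine 10 of these genes were called with digoxin, 8 higher and 2 lower (5 with library totals, 4 higher and 1 lower, with the median of all genes moved by -0.13). Only Elen_2528 and Elen_2529 stayed called in every fit without 1 library. Carbamate kinase Elen_1947 (log2 fold 2.55, SE 0.77, adjusted p = 0.0436) and ornithine carbamoyltransferase Elen_1948 (log2 fold 2.51, SE 0.70, adjusted p = 0.0325), known steps of arginine fermentation, were higher. Elongation factor G Elen_0960 was higher by a log2 fold of 3.65 (SE 0.69, adjusted p = 3.05e-05), with 102 of its 167 digoxin counts in replicate 2. Over 74 genes high in exponential cultures, that library stood at a median of 8.22% of the exponential level, against 0% and 1.03% in the others of its group, by which those genes were chosen. Elen_0960 did not pass the count filter, and so was not tested, without any 1 of the 3 digoxin libraries. This held even for replicate 1, which had only 7 of its 167 digoxin counts, as the filter depends on the depths of the libraries kept. The count fell to 2 without replicate 1 or 2 of the cultures without digoxin, and to 2 and 3 without replicates 1 and 2 of the digoxin cultures. Without replicates 1 and 2 of the cultures without digoxin the adjusted p was 0.0578 and 0.131 for Elen_0960, 0.811 and 0.901 for Elen_1947, and 0.508 and 0.926 for Elen_1948. Without replicate 2 of the digoxin cultures the log2 fold of Elen_1948 was 1.38 (adjusted p = 0.773), and without replicate 1 its adjusted p was 0.187. The adjusted p of Elen_1947 was 0.311 and 0.498 in those fits without replicates 1 and 2. Both calls were lost with library totals (adjusted p = 0.0798 for each) and with no filter (0.0685 for Elen_1947 and 0.0536 for Elen_1948), and without libraries under 10000 counts (0.0785 and 0.251, and 0.165 for Elen_0960). That of Elen_1947 was also lost with DESeq2 size factors (0.0685), DESeq2 (0.0632) and voom (0.0659). In the arginine deiminase pathway 2 of 5 tested members rose and 3 were not called, against 3 higher adjusted over the list alone (camera adjusted p = 0.00556, adjusted p = 0.446 with an estimated correlation). The 12 tested chaperones and proteases all had log2 folds above 0 with none called (median 0.84, camera adjusted p = 0.00332, adjusted p = 0.112 with an estimated correlation). At 1.25% arginine the 13 genes called lower with digoxin rested on libraries of 781 and 160 counts: with library totals 1 gene was called, higher, and the median log2 fold of all genes moved from -1.55 to 0, and without replicates 1 and 2 of the digoxin cultures the count was 4 and 7. Among these, cytochrome c assembly gene Elen_2583 (at least 1.6-fold lower) and Elen_2068 (at least 1.79-fold lower) were not called with library totals or without replicate 1 of the digoxin cultures, and Elen_2068 also not without replicate 2. The cytochrome list had 2 of 5 tested members lower (camera adjusted p = 0.0337, adjusted p = 0.686 with an estimated correlation).

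For 3 genes the digoxin effect at 0.25% arginine differed between stationary and exponential cultures. With digoxin, the mean of the sigma factor gene Elen_2728 went from 37.0 to 189 CPM in exponential and from 661 to 478 CPM in stationary cultures (difference in log2 fold -2.75, SE 0.52), and that of the degV gene Elen_1941 from 116 to 491 CPM and from 5193 to 4238 CPM (difference -2.47, SE 0.50). The ammonium transporter Elen_2526 went from 475 to 129 CPM in exponential and from 24.6 to 165 CPM in stationary cultures (difference 4.34, SE 0.89, on 2 counts in stationary cultures without digoxin). Each call was lost without either replicate of the stationary cultures without digoxin, or without replicate 1 of the exponential cultures without digoxin, and 0 genes were called in each of those 3 fits (edgeR adjusted p of Elen_2728 0.0894, 0.259 and 0.069). The call of Elen_2526 was also lost without stationary digoxin replicate 2, and that of Elen_1941 without replicate 2 of either exponential group. Without other libraries the count went up to 32 (stationary digoxin replicate 3), 18 and 7 (exponential digoxin replicates 3 and 1) and 5 (stationary digoxin replicate 1, and exponential replicate 2 without digoxin). At an unadjusted p under 0.05 there were 293 genes.

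Among stationary cultures without digoxin, genes of the arginine deiminase pathway went both ways with arginine. At 1.25% arginine carbamate kinase Elen_1947 stood at 40110 CPM (SD 21500, n = 3) against 875 CPM (SD 166, n = 2) at 0.25%, a log2 fold of 5.19 (SE 0.88), and ornithine carbamoyltransferase Elen_1948 was higher by a log2 fold of 4.41 (SE 0.77). The call of Elen_1948 was lost without libraries under 10000 counts (log2 fold 2.91, adjusted p = 0.0975). Arginine deiminase Elen_0153, in contrast, was lower (log2 fold -4.95, SE 0.82; 19480 to 830 CPM). Of the pathway's 5 tested members 3 rose, 1 fell and 1 was not called, the same adjusted over the list alone (camera adjusted p = 0.665, adjusted p = 0.769 with an estimated correlation). The third to rise, arginine deiminase Elen_1949 (log2 fold 1.42, SE 0.64, adjusted p = 0.047), lost its call without replicate 1 or 2 at 0.25% arginine and without replicate 1 or 2 at 1.25% arginine (adjusted p from 0.0627 to 0.303). All 5 tested members of the oxidative stress list fell, as they did adjusted over the list alone (camera adjusted p = 0.00517, adjusted p = 0.684 with an estimated correlation). Among them were the rubrerythrins Elen_0138 (log2 fold -5.96, SE 0.85) and Elen_0398 (log2 fold -5.28, SE 0.82) and catalase Elen_0128 (log2 fold -5.13, SE 0.80). The antitermination factor gene Elen_1880 rose from 162 CPM (SD 94.9) to 30120 CPM (SD 16390), and the C4-dicarboxylate carrier Elen_1568 fell from 22510 CPM (SD 5439) to 223 CPM (SD 198). L13 of the ribosome, Elen_0346, had 0 counts at 1.25% arginine, at least 13.7-fold lower. Of 464 genes tested by edgeR 249 were called, 99 higher and 150 lower. DESeq2 size factors gave 128 higher and 95 lower, and library totals 121 and 115, with the median of all genes 0.66 and 0.38 higher.

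Against exponential cultures, stationary cultures without digoxin had far lower levels of several genes of energy conversion. Because scaling changed the balance of directions, genes are described here where TMM, DESeq2 size factors and library totals called them in the same direction. All 7 genes of ATP synthase and all 5 of the NADH dehydrogenase list fell in this sense at both arginine concentrations. At 0.25% arginine Elen_1255 of the NADH dehydrogenase list went from 2619 counts to 1 (count ratio 201, exact 95% interval 36.0 to 7940), and ATP synthase beta subunit Elen_1045 from 2328 counts to 2 (count ratio 89.3, exact 95% interval 24.7 to 738). The hydrogenase large subunit Elen_1276 went from 5542 CPM (SD 283, n = 3) to 0 counts (n = 2), at least 164-fold lower. At 1.25% arginine it fell by a log2 fold of -5.52 (SE 0.60) with TMM, -6.2 with DESeq2 size factors and -4.27 with library totals. Of 51 ribosomal proteins 34 fell and 1 rose at 0.25%, and 25 fell and 0 rose at 1.25% arginine. Of 23 aminoacyl-tRNA synthetases 15 and 8 fell, of 13 genes of peptidoglycan and cell division 11 and 5, and of 11 hydrogenase genes 9 and 8. Over all 2355 genes tested, 635 and 416 fell in this sense. Catalase Elen_0128 fell at 1.25% arginine from 29170 CPM (SD 1929, n = 3) to 505 CPM (SD 455, n = 3), a log2 fold of -6.80 (SE 0.54) with TMM. With DESeq2 size factors it was -7.54 and with library totals -5.57. All 7 members of the oxidative stress list fell there. At 0.25% arginine 5 of those 7 fell.

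Log2 folds in this paragraph are from TMM unless another scaling is named, and their SEs leave out the differences between scalings. In stationary cultures the sigma 54 gene Elen_2875 rose by log2 folds of 6.92 (SE 0.50; 140 to 26710 CPM) at 0.25% and 6.31 (SE 0.48; 86.7 to 15740 CPM) at 1.25% arginine. With DESeq2 size factors these were 4.89 and 5.69, and with library totals 7.59 and 7.56. At 0.25% arginine the sigma factor gene Elen_2223 rose by a log2 fold of 7.13 (SE 0.40), the RelB antitoxin Elen_1183 by 6.96 (SE 0.47) and the XRE regulator Elen_2797 by 6.36 (SE 0.48). DESeq2 size factors gave 5.17, 5.01 and 4.38, and library totals 7.85, 7.7 and 7.08. Elen_2223, Elen_1183 and Elen_2797 rose at 1.25% arginine as well, by log2 folds of 3.89, 4.25 and 3.98. At 1.25% arginine the electron transfer flavoprotein genes Elen_2872 (log2 fold 6.82, SE 0.50) and Elen_2873 (log2 fold 5.87, SE 0.65) rose, as did the transporter Elen_1186 (log2 fold 6.99, SE 0.76). DESeq2 size factors gave 6.12, 5.21 and 6.29, and library totals 8.06, 7.09 and 8.21. Elen_2872 rose at 0.25% arginine as well (log2 fold 6.43, and 4.53 with DESeq2 size factors). Elen_2873 and Elen_1186 were not called there with DESeq2 size factors (edgeR adjusted p = 0.124 and 0.216). Over all 2355 genes tested, 192 rose at 0.25% and 243 at 1.25% arginine under all 3 scalings. LuxR regulators rose in 11 of 82 tested members at 0.25% and 13 at 1.25% arginine, with 1 lower at each, and Elen_0506 rose at both (log2 folds 4.38, SE 0.55, and 4.50, SE 0.61; 2.42 at 0.25% with DESeq2 size factors). Flavin reductases rose in 3 of 40 tested members at 0.25% (1 lower) and 14 at 1.25% arginine (0 lower), among them Elen_0107 (log2 fold 6.04, SE 0.86), which had too few counts to be tested without replicate 2 or 3 of the stationary cultures. The share of flavin reductases that rose at 0.25% arginine was no higher than that of all genes. Molybdopterin oxidoreductases went both ways, 4 higher and 4 lower of 30 tested at 0.25%, and 8 higher and 2 lower at 1.25% arginine.

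Of 2355 genes tested by edgeR, 1372 were called at 0.25% arginine (533 higher, 839 lower) and 1127 at 1.25% arginine (325 higher, 802 lower). The median log2 fold of all genes was -0.57 and -1.10. With TMM, unchanged genes in the simulations of these comparisons had medians of -0.36 and -0.99. Library totals gave 701 higher and 635 lower, and 537 higher and 416 lower, with medians of 0.12 and 0.13. DESeq2 size factors gave 192 higher and 1486 lower, and 243 higher and 1049 lower, with medians of -2.53 and -1.79. Under all 3 scalings 192 genes were higher and 635 lower at 0.25% arginine, and 243 and 416 at 1.25% arginine, so the balance of directions followed the scaling. Of these, 92 were higher and 308 lower at both. Camera called 10 lists at 0.25% and 13 at 1.25% arginine at the preset correlation and 0 with an estimated one. The lowest adjusted p with an estimated correlation was 0.0915, for the oxidative stress list at 1.25% arginine (1.52e-09 at the preset one). In the ribosomal list the preset adjusted p was 0.000137 at 0.25% (adjusted p = 0.37 with an estimated correlation) and 7.42e-09 at 1.25% arginine (adjusted p = 0.206). No call of Elen_0128, Elen_1045, Elen_1255, Elen_1276 or Elen_2875 was lost in any fit without 1 library.

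**Figure D5:**
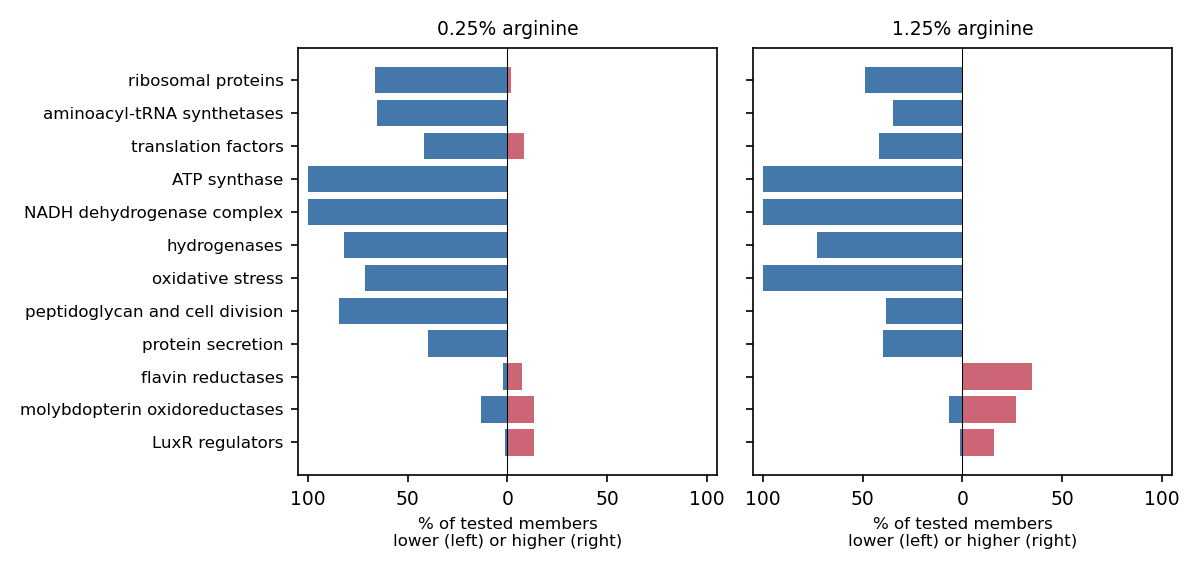
Share of tested members of 12 gene lists called lower (left, blue) or higher (right, red) in stationary than in exponential cultures under each of 3 scalings, without digoxin, at 0.25% and at 1.25% arginine. ATP synthase (7 genes) and the NADH dehydrogenase list (5 genes) reached 100% lower at both.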

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

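The tests of the Elen_0706 pattern below were predicted before they were run, but after the pattern itself had been seen, and the medians over genes called under all 3 scalings were added after the first medians were known.

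A test of the difference between 2 digoxin effects singled out 7 genes in exponential cultures, comparing 1.25% with 0.25% arginine. The differences in log2 fold were -2.83 for acetate/CoA ligase Elen_0706, -2.06 for Elen_0707, -7.01 for ornithine carbamoyltransferase Elen_0676, 2.33 for the ammonium transporter Elen_2526, 1.41 for ribosomal protein L11 Elen_2129, -1.73 for Elen_0740 and -1.81 for Elen_0742. The value of Elen_0676 rested, after rounding, on 1 count in the 1.25% arginine digoxin cultures and 3 in the 0.25% cultures without digoxin. The same kind of test, comparing stationary with exponential cultures at 0.25% arginine, singled out the sigma factor gene Elen_2728 (-2.75), the degV gene Elen_1941 (-2.47) and Elen_2526 (4.34).

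Among the exponential groups, Elen_0706 and Elen_0707 were low only at 0.25% arginine without digoxin, and 3 technical explanations were tested. Thinning every exponential library to 293486 counts left differences of -2.87 for Elen_0706 and -2.11 for Elen_0707, and without any 1 library that of Elen_0706 stayed between -3.16 and -2.63 (largest adjusted p 0.0052), which argues against depth and against a single library. Had those cultures been nearer to stationary phase, a median log2 fold with digoxin of 0.5 or more was predicted for the genes that fall at stationary phase, and under 0.3 if not, and it was 0.02 over 704 such genes chosen with TMM (bootstrap 95% interval -0.02 to 0.06) and 0.02 over 416 lower under all 3 scalings (-0.04 to 0.08). By that prediction these medians count against this explanation, and 52% of the 704 genes lay above 0. The samples do not show, however, which of these genes fall first. The genes that rise at stationary phase had medians of -0.17 (125 genes, -0.32 to -0.03) and -0.18 (115 under all 3 scalings, -0.32 to -0.04), the direction that this explanation gives. Weighing the genes that rise was not part of the written prediction. A difference in growth stage therefore stays open, as does whether the cultures of this group were handled apart from the others, which was not analysed here.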

How the results depend on the processing

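Of 3392 values for named genes under the alternatives, leaving out Elen_2528 and Elen_2529 with digoxin, 3067 kept their direction and side of the threshold and 15 reversed. Another 289 kept their direction but lost the call, whatever the size of the fold, and 21 gained a call. Fits in which a gene was not tested gave no value and are not counted here. The increases of Elen_2528 and Elen_2529 held under every alternative in exponential cultures (log2 folds without 1 library 8.19 to 9.12 and 7.11 to 7.51 at 0.25%, 7.51 to 8.35 and 8.34 to 8.99 at 1.25% arginine) and in stationary cultures at 0.25% arginine (6.84 to 10.45 and 6.88 to 11.65). A further 3 reversals were theirs: in stationary cultures at 1.25% arginine Elen_2529 reversed to 1.59 with DESeq2 and 1.21 with voom (leaving out 1 library, -4.75 to -4.14), and Elen_2528 to -3.37 without digoxin replicate 1 (highest 6.22). A library left alone in its group was assumed to vary like the other groups.

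Counts of called genes moved as follows, and the cause was not tested. Digoxin, exponential, 0.25% arginine: DESeq2 129, voom 94, without 1 library 34 to 127. At 1.25%: voom 150, without 1 library 28 to 41. Digoxin, stationary, 0.25%: stricter filter 19, DESeq2 23, all 22 libraries 24, without libraries under 1000 counts 16, library totals 5, without 1 library 2 to 14. At 1.25%: DESeq2 size factors 1, stricter filter 1, DESeq2 3, voom 4, all libraries 7, library totals 1, without 1 library 4 to 18. Arginine, exponential, no digoxin: all libraries 60, without 1 library 44 to 120. With digoxin: DESeq2 142, voom 235, all libraries 49, without 1 library 8 to 185. Arginine, stationary: no filter 416, stricter filter 161, all libraries 543, without 1 library 171 to 219. Phase at 0.25%: without 1 library 1033 to 1346. At 1.25%: stricter filter 731 (fewer genes tested), without 1 library 863 to 1104. Digoxin by arginine: all libraries 4, without 1 library 2 to 8. Digoxin by phase: DESeq2 size factors 16, no filter 9, stricter filter 7, DESeq2 79, voom 1, only the groups compared 1, without libraries under 1000 counts 12 and under 10000 counts 14, library totals 5, without 1 library 0 to 32.

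With an estimated correlation 0 lists were called in every comparison, against 3 for digoxin in exponential cultures at 1.25%, 2 and 1 for digoxin in stationary cultures at 0.25% and 1.25%, 1, 2 and 1 for arginine (exponential without and with digoxin, stationary) and 10 and 13 for phase. The stationary list at 1.25% arginine was also lost (0) with DESeq2 size factors and with library totals. Reversed in arginine comparisons, where none was called except Elen_1949 in stationary cultures: Elen_0153 (0.02, lowest -0.33) without replicate 3 at 0.25% and Elen_0670 (0.24, lowest -0.98) without replicate 2 at 1.25%, both exponential without digoxin. With digoxin: Elen_0413 (0.17, 0.41 and 0.12, lowest -1.88) and Elen_1949 (0.04, lowest -0.33), each without 1 library. Stationary: Elen_0413 with DESeq2 size factors 0.46, stricter filter 0.49, DESeq2 0.28, without libraries under 10000 counts 0.40, library totals 0.19, and without 1 library 0.40, 0.54 and 0.38 (lowest -0.67). Elen_1949 was -0.24 without libraries under 10000 counts. The cause was not tested.

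Upper-quartile scaling could not be fitted to the stationary libraries or to all 22 and was not run there. A planned minimum of 100000 counts removed no exponential library and left no stationary comparison. No paired analysis was possible because the labels link no library of one group to a library of another.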

Other observations

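Replicate 2 of the stationary 1.25% arginine digoxin group, with 160 counts, resembled stationary cultures at 0.25% arginine. Its log likelihood was 175.2 higher under the profile of stationary 0.25% arginine cultures with digoxin than under that of stationary 1.25% arginine cultures without digoxin (173.3 higher for 0.25% arginine without digoxin). In a calibration chosen after this was seen, 1000 draws of 160 counts from each of 5 stationary 0.25% arginine libraries were all nearer to 0.25% arginine (lowest 57.9), and 0 of 1000 from each of 3 stationary 1.25% arginine libraries were (highest -45). Arginine deiminase Elen_0153 had 8 of the 160 counts, 5%, against 1.948% at 0.25% and 0.083% at 1.25% arginine, and the C4-dicarboxylate carrier Elen_1568 had 5, 3.12%, against 2.251% and 0.022%. The label of this library, or the source of its few counts, may therefore be wrong, but a true effect of digoxin at 1.25% arginine cannot be excluded with 1 such library. Replicate 1 (781 counts) was nearest to stationary 1.25% arginine cultures without digoxin (difference for the next profile -674.6), and no profile with digoxin was compared at that phase and concentration. In a test added after this was seen, its 0 counts of Elen_2529 allowed up to 3840 CPM. The lowest mean of the other digoxin groups was 1799 CPM, in exponential 1.25% arginine cultures. In stationary 0.25% arginine cultures with digoxin the mean was 14260 CPM, above that limit. Elen_2528 had 1 count in replicate 1, or 1280 CPM, against means of up to 29.9 CPM in the groups without digoxin. On so few counts, whether replicate 1 came from a culture with digoxin stays open.

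Replicate 2 of the stationary 0.25% arginine digoxin group was closer to the exponential libraries than the others of its group. Over 74 genes high in exponential and low in the other 2 libraries, its median level was 8.22% of the exponential level, against 0% and 1.03%. Reads carried over from exponential libraries would give all these genes a similar share, but the upper over the lower quartile of the share was 5.88 (bootstrap 95% interval 3.53 to 8.86), where 4 or more had been predicted without carry-over. In comparisons added after that result, it lay between 4.13 and 6.5 against single exponential groups and between 3.63 and 12.7 against single exponential libraries. Elen_0706 had 0 counts where 62.1 were expected on average, though only 4.2 if the reads came from the 0.25% arginine cultures without digoxin. Its neighbour Elen_0707, at a mean of 7719 CPM in the exponential libraries, also had 0 counts, and 9 of the 74 genes had 0 in all. Since the bootstrap interval reached below the predicted 4, carry-over stays open, and a culture that had entered stationary phase later was not tested.

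Called genes lay next to each other on the chromosome, in line with shared transcripts. In exponential cultures 14 genes called with digoxin at 0.25% arginine were followed by a gene called in the same direction, against a mean of 0.69 and at most 6 in 10000 random draws. The numbers were 21 (0.71 and 6) at 1.25% arginine and 46 (5.28 and 15) for arginine without digoxin. Each gave a permutation p = 1e-04, the smallest that 10000 draws can give. Transcripts were not mapped, so this could also arise from separate promoters under the same control.

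Other splits of the libraries into groups of equal size were fitted in the same way. With 3 libraries a side there are 10 splits, too few for a share under 0.05, and in each comparison only 1 split, the real one, reached its own number of called genes. Each of the other splits mixed the real groups on both sides, which can widen the spread and lower the number called. The real number and the highest of the others were 59 and 5 for digoxin at 0.25%, 60 and 0 at 1.25%, 156 and 0 for arginine without digoxin, 74 and 7 with digoxin, and 1127 and 17 for phase at 1.25% arginine. For the difference of digoxin effects between arginine concentrations, 100 splits were fitted, the real one and a random sample of the others. Of these 100, 3 gave 7 or more genes, the real one included, with the highest of the others giving 9.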
